A study of Halobacterium salinarum NRC-1 with 30 samples.

How the data were processed

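Total RNA of the archaeon Halobacterium salinarum NRC-1 was measured on 30 two-channel spotted arrays, which set 15 serial samples of one turbidostat culture against a common reference RNA. Per the labels, the culture was kept for 12 h near oxygen saturation (90 to 100%, agitation at 1200 rpm) at 37 °C and was then brought quickly to 0 to 10% oxygen (250 rpm, air flow stopped), and 10 mL of cells were harvested at each time. The reference came from a mid-logarithmic culture shaken at 225 rpm. Each time point was hybridised on 2 arrays, one with the sample in the dye Alexa 532 and one with the dyes exchanged, so that the sample was in Alexa 647.

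The deposited table holds 1 value per spot and array, and the values behave as log ratios of the 2 channels. Steps of background correction and normalization within arrays, and the tools used for them, are not given in the sources used here. The base of the logarithm is not stated either. Where a fold is given below, base 10 was assumed, under which a 2-fold change equals 0.301. All other values are in the units of the table. The arrays were not median-centred in the deposited table: medians were 0.101 to 0.231 for arrays with the sample in Alexa 532 and -0.0185 to 0.143 for those with it in Alexa 647. The swapped arrays had been turned before deposit, since their zeros are written with a minus sign and the change from transition to the late time points (110 to 380 min) correlated between the orientations at r = 0.886 across targets, with a slope of 0.837. No sign was therefore turned here. That the ratio is sample over reference is likely, from the naming of the arrays, but it is not stated, and all signs and directions given here would turn together if it ran the other way.

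The table has 10752 spots for 2688 targets, each spotted as an adjacent pair that is repeated once elsewhere on the array. Within an array, adjacent spots of a target correlated at r = 0.777 to 0.965, against 0.165 to 0.443 for adjacent spots of different targets. The 4 spots of a target were averaged. The platform table gives 1 gene symbol for 532 spots (133 targets), several symbols for 0 spots and none for 10220 spots (2555 targets). Unnamed targets stayed in all tests and counts and are given by number. Exact zeros made up 0 to 21.7% of the spots of an array (median 2.9%). They were treated as missing because of the level of the other spots of such targets. The median of that level per array ran from -0.054 to 0.582, with a median of 0.214 over arrays, so on some arrays it was near 0. Signal over background is not part of the table, so precision rests on the number of arrays alone.

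The array pair of a time point was averaged and counted as 1 value. Titles place 4 time points (0, 5, 10 and 20 min) in the transition and 11 (25, 30, 35, 45, 55, 70, 110, 160, 200, 290 and 380 min) in low oxygen. With 1 sample per time point from 1 culture, p-values measure only the spread between time points, not between cultures. A target was tested when it had a value at 3 or more transition and 8 or more low oxygen time points, which left 2659 targets (132 with a symbol), and 29 were not tested. Calculations used R 4.3.3 with limma 3.58.1 (lmFit and eBayes), and Benjamini-Hochberg adjusted p under 0.05 was the threshold throughout. The 3 tests were low oxygen minus transition, a moderated F test of a natural spline with 3 degrees of freedom on log2 of time plus 10 min, and the slope per doubling of time over the 11 low oxygen time points. The change from 0 min at each time point has no replicate and was given without a test. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

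Gene lists were tested with limma's camera (preset inter-gene correlation 0.01, and estimated as a check) and fry, adjusted over the lists, on the 2414 targets with a value at all 15 time points. Of 29 lists, 22 were fixed in advance and 7 were added once the gene symbols on the array were known and before any test was run: histidine synthesis, histidine breakdown, other amino acid synthesis, glutamate dehydrogenases, cofactor synthesis, protein translocation and nucleotide interconversion. A list needed 3 genes with a value at all 15 time points for a test, which 15 lists had. Histidine breakdown has 3 measured genes, not all of them complete, and was not tested as a list. For 8 lists (dimethyl sulfoxide respiration, gas vesicles, terminal oxidases, ATP synthase, RNA polymerase, general transcription factors, oxidative stress and transposases) no member carries a symbol among the spots, and they were not analysed here. Markers of other cell types were not scored, because the culture held a single archaeon.

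The grouping, the tests, most alternatives and the rule for naming genes were set before the data were examined. That rule took, among called genes with a symbol, the 10 with the largest rise and the 10 with the largest fall between phases, up to 4 called members of each list (or the member with the smallest p), the 5 largest rises and falls of the slope, the 5 smallest p-values of the time course, and bat and arcA in any case. Of the other genes it always named, none carries a symbol here. The rule gave 38 genes, of which 1 is not reported here. The planned tests assumed log2 values, and since the base is unknown the deposited values were used unchanged.

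Alternatives were median-centring of each array, scaling to a common median absolute deviation, medians over spots, either dye orientation alone, all 30 arrays in one fit with a dye term and the time point as a random block, complete targets only, a limit on the gap between orientations, another variance model, other splines and time scales, parts of the low oxygen phase, each time point left out, an exact permutation test per target and a 2-fold limit. The tests were checked on simulated data with 2414 targets, 200 of them changed. Of phase differences of 0.1, 0.2 and 0.3, the test found 49.3%, 100% and 100%. The time course test found 7.46%, 80.6% and 100% of changes of those sizes, and the slope test 8.96%, 77.6% and 95.5%. Among simulated calls, 6.74% were false for the phase, 6.72% for the time course and 3.2% for the slope. Simulated data without any change gave 0 calls in each test when time points were independent, and 91, 450 and 103 calls for the phase, the time course and the slope when neighbouring time points were correlated at 0.5. In the residuals of the data, the median correlation of neighbouring time points was 0.113, -0.242 and -0.131. Such residual correlations are lowered by the fit itself and cannot show that time points were independent. The simulations drew the errors of each target separately, so they hold no errors shared by many targets of an array. Their rates of false calls therefore need not hold for these data.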

Results

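Transcript levels of Halobacterium salinarum NRC-1, a salt-loving archaeon, were followed through a shift of one culture from high to low oxygen, in a repeat of an earlier oxygen series with a longer hold at high oxygen. Samples were taken at 15 time points, 4 during the transition (0 to 20 min) and 11 in low oxygen (25 to 380 min), each compared with a common reference on 1 dye-swapped pair of arrays. Values are deposited log ratios of unstated base, with sample over reference as the likely direction. The 2 arrays of a time point correlated across targets at r = -0.0158 (35 min) to 0.911 (380 min), with a median of 0.672. The pairs of 20, 25 and 35 min stood lowest, at 0.191, 0.203 and -0.0158, and the deviations of their arrays with the sample in Alexa 647 correlated best with the Alexa 532 array of 0 min, at 0.745, 0.727 and 0.710. Arrays with the sample in Alexa 532 correlated among themselves at 0.812 to 0.967, and those with it in Alexa 647 at 0.145 to 0.916. The median over all targets moved from 0.0643 at 0 min to 0.175 at 380 min, so results are also given with every array centred on its median.

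The first comparison asked which transcripts differed between the transition and the low oxygen phase. The gene pan1, for a proteasome-activating nucleotidase (the ATPase that feeds proteins into the proteasome), rose most among the genes with a symbol, by 0.320 ± 0.0397 (SE, 4 against 11 time points; 2.09-fold if base 10; adjusted p = 7.75e-05). It stood above its highest transition value (0.274) at all 11 low oxygen time points, the lowest of which was 0.391. In contrast, psmB, for a subunit of the 20S proteasome core, fell by 0.0974 ± 0.0300 (adjusted p = 0.0245). It lay below its lowest transition value at 11 of 11 time points, but at 45 min this was almost a tie (0.01704 against 0.01707 at 5 min). Transcripts of htr1, the transducer of sensory rhodopsin I, rose by 0.154 ± 0.0307 (adjusted p = 0.00522; 11 of 11 time points), and those of dpsA, a ferritin-like protein, by 0.129 ± 0.0298 (adjusted p = 0.0102; 11 of 11). The largest fall among called genes with a symbol was that of glyA (serine hydroxymethyltransferase), which fell by 0.128 ± 0.0327 (adjusted p = 0.0157; 11 of 11 time points below the transition mean).

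Further rises by the same test included those of hutG of histidine breakdown (0.136, adjusted p = 0.0166, 10 of 11 time points), purB for adenylosuccinate lyase (0.133, adjusted p = 0.0412, 9 of 9), mamA (0.120, adjusted p = 0.0256, 11 of 11) and nadA for quinolinate synthase (0.118, adjusted p = 0.0238, 11 of 11). Here and below, such counts are of low oxygen time points above, or for falls below, the transition mean. For purB and nadA that mean rests on 3 time points. The genes pheA (prephenate dehydratase) and mutL (mismatch repair) rose by 0.117 and 0.113, with adjusted p = 0.0314 and 0.0238, each higher at 11 of 11 time points. Besides glyA and psmB, the falls were those of gdhA2 for a glutamate dehydrogenase (-0.116, adjusted p = 0.0142, 11 of 11), cmk for cytidylate kinase (-0.107, adjusted p = 0.0186, 10 of 11) and orc8 of the Orc1/Cdc6 family of replication initiators (-0.0933, adjusted p = 0.0428, 11 of 11). Counted beyond the most extreme transition value instead, purB had 8 time points, mamA 7, nadA 9, pheA 8, gdhA2 9 and orc8 7. For hutG, mutL and cmk the count stayed the same. Among 132 tested genes with a symbol, 21 changed, 16 higher and 5 lower. The bacterio-opsin activator gene bat differed by 0.0602 (adjusted p = 0.197; higher at 10 of 11 time points), which did not pass.

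Over all 2659 targets, 785 changed between phases, 673 higher and 112 lower in low oxygen (85.7% higher). After median-centring, 333 changed, 148 higher and 185 lower (44.4% higher), and 257 of these were called with the same sign in both. With centring 12 genes with a symbol were called, 3 higher (pan1, htr1 and hutG) and 9 lower, among them all 5 named falls, while dpsA no longer passed (0.0854, adjusted p = 0.0771). Without the 0 min time point the number of called targets was 60, and without the 20 min time point it was 193. Of 18 called genes named by the rule, 2 (pan1 and htr1) still passed without 0 min, 13 without 5 min, 9 without 10 min and 7 without 20 min. Some had too few values to be tested there, namely purB without 0 min, nadA without 10 min, and both without 5 min or 20 min. For psmB the adjusted p was 0.110 without 0 min, 0.0524 without 10 min and 0.0606 without 20 min, and for glyA it was 0.106 without 0 min. On arrays with the sample in Alexa 647 alone, 34 targets were called, 18 higher and 16 lower, and pan1 was the only named gene among the 18 to pass (0.322, adjusted p = 0.0157). Of these 34, 29 were also called with the same sign on Alexa 532 arrays alone. All 785 differences had the same sign in both orientations, but these targets were chosen on the mean of both, which favours such agreement.

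**Figure D1:**
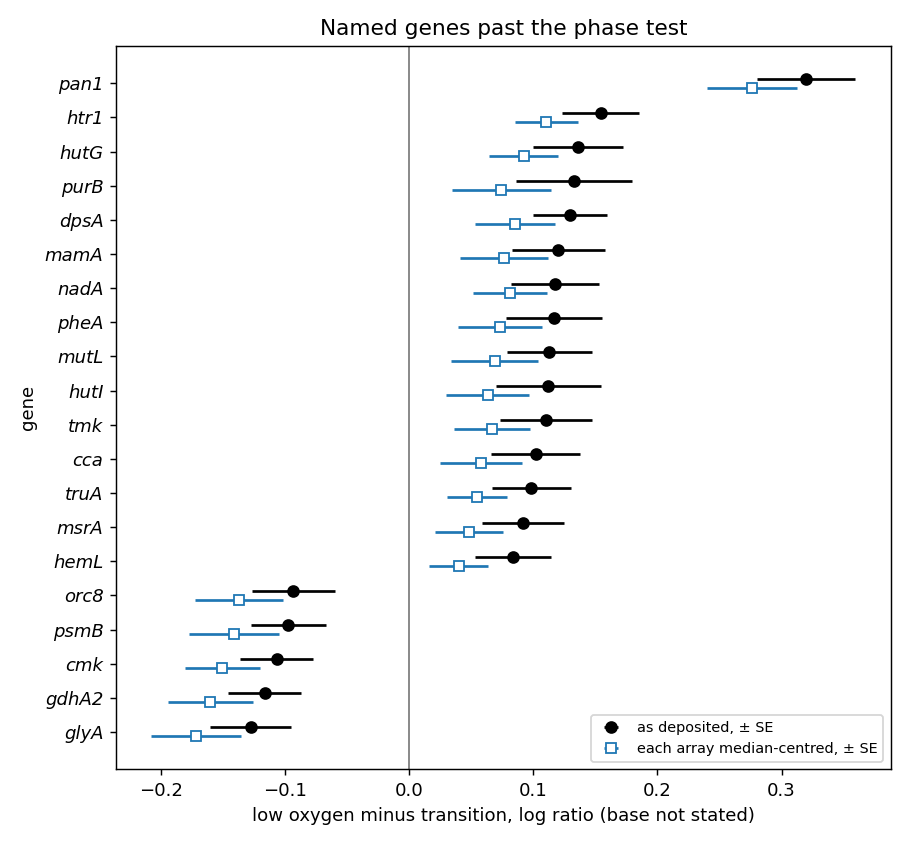
Low oxygen minus transition difference of 20 of the 21 genes with a symbol that passed the phase test, in deposited log ratio units on the horizontal axis and 1 gene per line. Bars are 1 standard error from 4 transition and 11 low oxygen time points, except for purB (3 and 9), nadA (3 and 11) and hutI (4 and 10). Black points are values as deposited and open blue squares values after median-centring of each array; pan1 stands at 0.320 as deposited and 0.276 centred.

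Gene lists were then compared between phases. In the chaperone and proteasome list, 1 of 6 genes rose (pan1), 1 fell (psmB) and 4 did not pass, and the counts adjusted over the list alone were the same (1 higher, 1 lower). Of 8 genes of DNA replication and repair, 2 rose, mutL among them, orc8 fell and 5 did not pass, with 2 higher and 1 lower adjusted over the list alone. Of 6 phototrophy genes, htr1 rose and 5 did not pass (1 adjusted over the list alone), and of 11 motility and chemotaxis genes, which include htr1, 1 rose and 10 did not pass (1 adjusted over the list alone). Fry found the phototrophy genes moving upward on balance (adjusted p = 0.0114), with a mean difference of 0.0627 against no change, but after centring its adjusted p was 0.263, and camera did not set them apart from other targets (adjusted p = 0.717). Among 12 genes of nucleotide biosynthesis purB rose and 11 did not pass, with 0 called by limma adjusted over the list alone (2 at unadjusted p under 0.05, purB and pyrF). Of 5 genes of nucleotide interconversion tmk (thymidylate kinase) rose by 0.111 (adjusted p = 0.0323, 10 of 11 time points) and cmk fell, with 2 higher and 1 lower adjusted over the list alone.

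Of 3 genes of histidine breakdown, hutG and hutI (0.112, adjusted p = 0.0490, 10 of 10 time points) rose, and all 3 passed when adjusted over the list alone. In other amino acid synthesis, pheA rose, glyA fell and 7 of 9 did not pass, with 1 higher and 1 lower adjusted over the list alone. Of 3 glutamate dehydrogenases, gdhA2 fell and 2 did not pass (1 adjusted over the list alone). Of 10 genes of cofactor synthesis, nadA and hemL of tetrapyrrole synthesis (0.0836, adjusted p = 0.0438, 10 of 11) rose and 8 did not pass, with 1 adjusted over the list alone.

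For 11 lists limma called 0 genes between phases, over all targets and adjusted over the list alone. The member with the smallest p is given for each. It was arcC (carbamate kinase) among 2 genes of arginine fermentation (mean 0.346 in transition, 0.478 at 25 to 70 min and 0.348 at 110 to 380 min). For NADH and succinate dehydrogenases (2 genes) it was sdhC, for the TCA cycle (6) mdh (malate dehydrogenase), and for the ribosomal protein list (1) rpl12p. It was cbiQ among 4 of cobalamin synthesis, moaA among 2 of the molybdenum cofactor, proS among 12 aminoacyl-tRNA synthetases and tpiA among 3 of glycolysis. It was phoU as the 1 gene of phosphate and iron uptake, hisG among 6 of histidine synthesis and secY among 3 of protein translocation. At unadjusted p under 0.05, limma counted 7 genes over these 11 lists, namely mdh, cbiQ, moaA, proS, lysS, hisG and secY. On Alexa 532 arrays alone proS (-0.128, adjusted p = 0.0191), sdhC (-0.115, adjusted p = 0.0337) and hisG (0.113, adjusted p = 0.0347) passed, while on Alexa 647 arrays sdhC stood at -0.00193 (adjusted p = 0.983). After centring mdh (-0.143, adjusted p = 0.0382), cbiQ (-0.101, adjusted p = 0.0396) and lysS (-0.105, adjusted p = 0.0241) passed.

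Camera placed 2 of 15 lists apart from other targets. The mean difference of the 6 TCA cycle genes minus that of other targets was -0.0988 (adjusted p = 0.0144), which became adjusted p = 0.358 with an estimated correlation and 0.0617 without the 0 min time point. The 12 aminoacyl-tRNA synthetases stood at -0.0529 against other targets (adjusted p = 0.0431; adjusted p = 0.358 with an estimated correlation). Their adjusted p was 0.227 without 0 min, 0.0725 without 25 min, 0.0643 without 30 min, 0.0563 without 55 min and 0.0563 without 110 min. Neither Alexa 532 nor Alexa 647 arrays alone called the synthetases (adjusted p = 0.101 and 0.137). After centring both lists missed the threshold (adjusted p = 0.0658 and 0.0547). Against genes with a symbol only, camera called neither list (adjusted p = 0.0972 and 0.204).

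The second comparison asked which transcripts changed smoothly over the whole course. The 5 smallest p-values among genes with a symbol belonged to rpl12p, for the L12 protein of the ribosomal stalk (adjusted p = 5.04e-13), pan1 (1.61e-09), ndk for nucleoside diphosphate kinase (5.06e-07), rimI for an acetyltransferase (2.42e-06) and arcA for arginine deiminase (1.86e-05). Transcripts of rpl12p stood at 0.137 at 0 min, peaked at 0.287 at 25 min and reached -0.502 at 380 min, a range of 6.14-fold if base 10. Those of arcA were at 0.146 at 0 min and -0.0325 at 5 min, peaked at 0.443 at 45 min and came to -0.103 at 200 min and 0.00719 at 380 min. In contrast, pan1 went from 0.0543 at 0 min to 0.600 at 200 min, with means of 0.440 over 25 to 70 min and 0.545 over 110 to 380 min. In all, 1503 of 2659 targets changed over time, and 970 after centring, including 63 genes with a symbol as deposited. The 5 genes passed in each orientation alone and after centring.

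**Figure D2:**
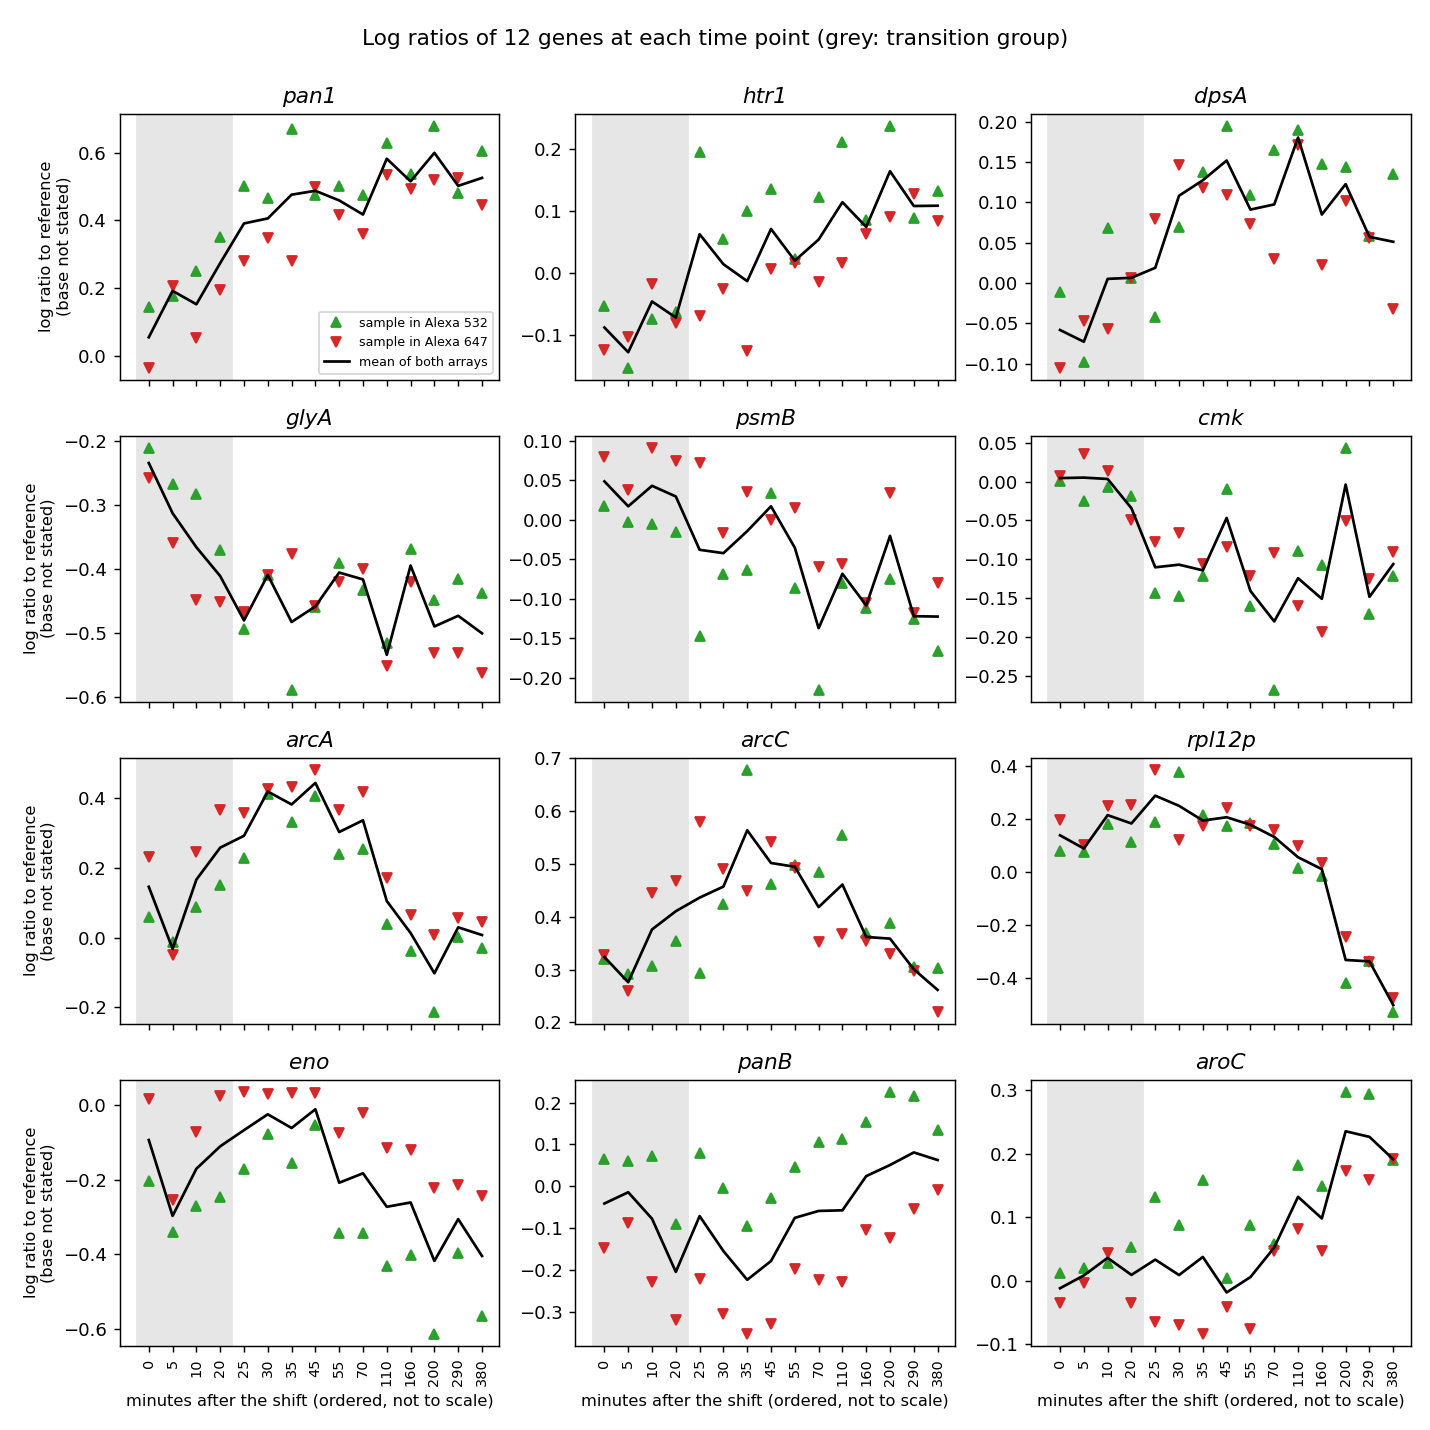
Log ratio (deposited units, vertical axis) against time in minutes (horizontal axis, in order and not to scale) for 12 genes, 1 panel each, with green upward triangles for arrays with the sample in Alexa 532, red downward triangles for those with it in Alexa 647, and a black line for their mean; the grey band marks the transition. The mean of pan1 is 0.391 or higher from 25 min on, arcA peaks at 0.443 at 45 min and rpl12p ends at -0.502.

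The third comparison asked whether transcripts went on moving within low oxygen. Among genes with a symbol, the steepest fall was that of rpl12p, at -0.189 per doubling of time (adjusted p = 6.70e-13), followed by arcA at -0.126 (adjusted p = 2.24e-08), eno (enolase) at -0.0982 (adjusted p = 1.03e-07), ndk at -0.0913 (adjusted p = 2.56e-07) and rimI at -0.0886 (adjusted p = 2.18e-07). The steepest rises among them were those of panB at 0.0654 (adjusted p = 7.13e-05), aroC (chorismate synthase) at 0.0599 (adjusted p = 0.000154) and deoC (deoxyribose-phosphate aldolase) at 0.0545 (adjusted p = 0.000910). They were followed by mch at 0.0536 (adjusted p = 0.000496) and hutI at 0.0532 (adjusted p = 0.000930). These 10 genes passed after centring and without any 1 of the 11 time points, but aroC, deoC, mch and hutI missed the threshold on arrays with the sample in Alexa 532 alone (adjusted p = 0.183, 0.432, 0.174 and 0.508). The slope of bat was 0.0292 (adjusted p = 0.0506), 0.0105 after centring (adjusted p = 0.559) and -0.00685 on Alexa 532 arrays alone, and as deposited it passed without 25 min (0.0401, adjusted p = 0.0146), 110 min (0.0303, adjusted p = 0.0472), 160 min (0.0308, adjusted p = 0.0479) or 200 min (0.0346, adjusted p = 0.0276). Over all targets 1110 had a slope past the threshold, 876 upward and 234 downward (78.9% upward). After centring there were 582, 176 upward and 406 downward (30.2% upward), of which 410 were called with the same sign in both, and without 380 min there were 635. Alexa 532 arrays alone gave 151, 51 upward and 100 downward, and Alexa 647 arrays alone 1448, 1187 upward and 261 downward. Of 132 genes with a symbol, 48 passed, 25 upward and 23 downward, and after centring 39 passed, 6 upward and 33 downward.

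Genes of the TCA cycle and of arginine fermentation fell within low oxygen. Of 6 TCA cycle genes 5 fell, among them icd (isocitrate dehydrogenase) at -0.0575 and sucC (succinyl-CoA synthetase) at -0.0559 per doubling, while mdh was at -0.00729 (adjusted p = 0.692), and 5 passed adjusted over the list alone. Camera set this list apart from other targets by -0.0513 (adjusted p = 0.00120; adjusted p = 0.101 with an estimated correlation), and against genes with a symbol only the adjusted p was 0.0687. Both arginine fermentation genes fell, arcA at -0.126 and arcC at -0.0566 (2 adjusted over the list alone). Of 3 glycolysis genes, eno and tpiA (-0.0360) fell and 1 did not pass (2 adjusted over the list alone), and of 2 genes of NADH and succinate dehydrogenases, sdhC fell (-0.0403; 1 adjusted over the list alone). The 1 gene in the ribosomal protein list, rpl12p, fell (1 adjusted over the list alone). That list took only symbols starting with rpl or rps, so it left out rpmC and does not stand for all ribosomal protein genes.

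Other lists held rises or both directions. The upward calls that passed after centring as well were those of panB, aroC, deoC, mch, hutI and htr18. All 3 genes of histidine breakdown rose (3 adjusted over the list alone), but the orientations differed. From 25 to 380 min on Alexa 532 arrays, hutG went from 0.607 to 0.481 and hutU from 0.528 to 0.463. There hutI went from 0.413 to 0.571, but its slope missed the threshold, as given above. On Alexa 647 arrays hutG went from 0.115 to 0.383, hutU from 0.0507 to 0.295 and hutI from 0.0186 to 0.323. All these starts rest on the 25 min pair, which correlated at only 0.203. At 30 min hutG stood at 0.408 on Alexa 532 arrays and 0.208 on Alexa 647 arrays, so from there it ended higher on both. For hutU the 30 min values were 0.514 and 0.0829, so its orientations still differed. Of 6 genes of histidine synthesis 3 rose, among them hisD (0.0427) and hisG (0.0410), while hisI fell (-0.0330). Adjusted over the list alone, 3 of these were higher and 1 lower. Of 11 motility and chemotaxis genes 4 transducer genes rose, htr18 (0.0529), htr7 (0.0430), htr6 (0.0299) and htr1 (0.0283), and 7 did not pass (4 adjusted over the list alone). In nucleotide biosynthesis purB rose (0.0454) and guaB for IMP dehydrogenase (-0.0754), pyrB (-0.0315) and pyrI (-0.0321) fell, with 8 of 12 not past the threshold and 1 higher and 3 lower adjusted over the list alone. In nucleotide interconversion 3 of 5 rose, deoC among them, and ndk fell (3 higher and 1 lower adjusted over the list alone). Among 6 chaperone and proteasome genes pan1 (0.0351) and panB rose and dnaK (-0.0799) fell, with 2 higher and 1 lower adjusted over the list alone; panB is also the symbol of a pantothenate synthesis gene, and which product the spot stands for is open.

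Of 12 aminoacyl-tRNA synthetases serS (0.0469) and glyS (0.0323) rose, proS (-0.0330) fell and 9 did not pass (2 higher and 1 lower adjusted over the list alone). In other amino acid synthesis 2 of 9 rose, aroC among them (2 adjusted over the list alone). In cofactor synthesis 2 of 10 rose and 1 fell (1 higher and 1 lower adjusted over the list alone). Of 6 phototrophy genes htr1 rose, and of 8 genes of DNA replication and repair 1 rose, with 0 called by limma adjusted over the list alone in either (2 and 1 at unadjusted p under 0.05). Limma called 0 genes of cobalamin synthesis (4 genes), molybdenum cofactor (2), phosphate and iron uptake (1), glutamate dehydrogenases (3) and protein translocation (3), by the same slope test, over all targets and adjusted over the list alone. At unadjusted p under 0.05, 1 gene of these 5 lists, gdhA1, was counted.

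The change from 0 min was given at each time point without a test. Every such change rests on the single 0 min pair, whose 2 arrays correlated at 0.465. On its Alexa 647 array 94 targets had no value. By 380 min, rpl12p had changed by -0.639 from 0 min (4.36-fold lower if base 10), pan1 stood 0.472 higher (2.96-fold if base 10) and eno had changed by -0.311. Targets at least 2-fold from 0 min, if base 10, numbered 4 at 5 min, 29 at 70 min, 90 at 110 min, 72 at 160 min, 125 at 200 min, 271 at 290 min and 331 at 380 min. At 380 min 263 of these were higher and 68 lower, and after centring 193 passed this size, 21 higher and 172 lower. In both orientations alike, 131 were higher and 46 lower. The difference between orientations in this change, divided by 2, had an SD over targets of 0.0434 at 380 min. It was 0.103 at 25 min and 0.102 at 35 min.

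**Figure D3:**
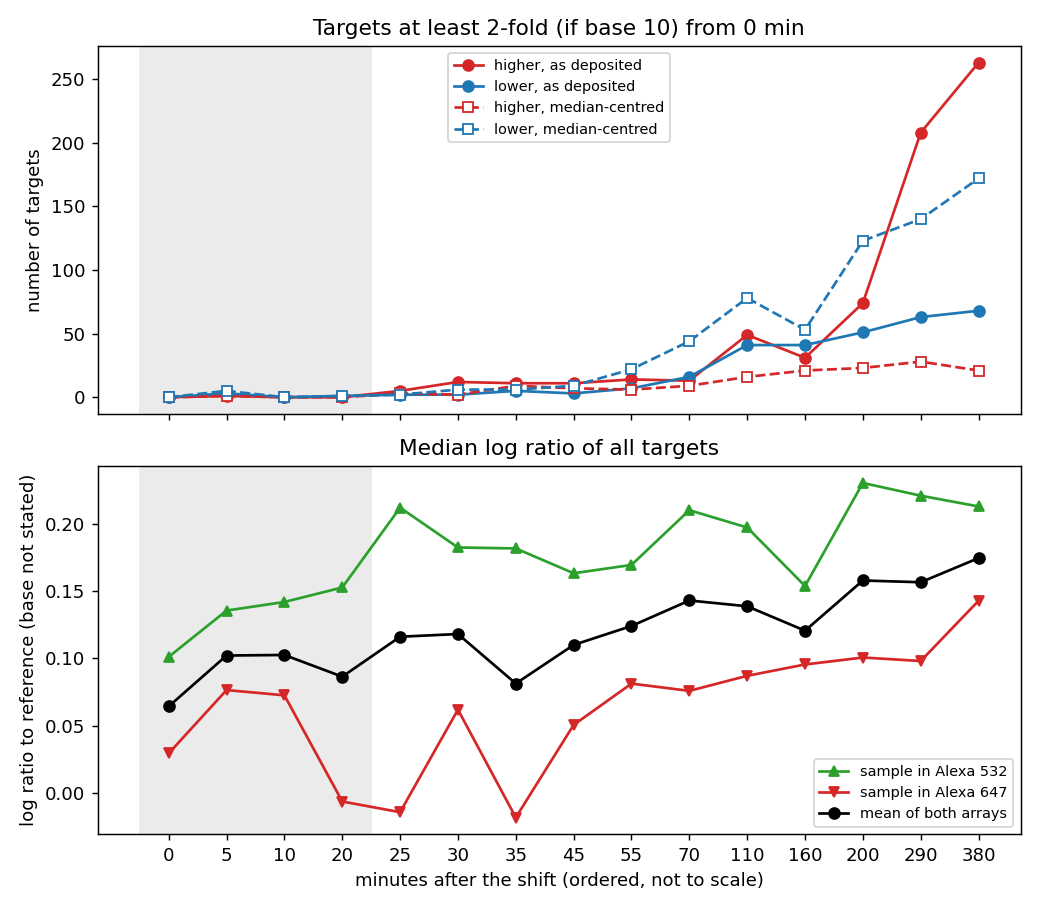
Upper panel, number of targets (vertical axis) at least 2-fold from 0 min if the values are base 10 logarithms, higher and lower, as deposited and after median-centring, against time in minutes in order and not to scale; lower panel, median log ratio of all targets per orientation at the same times. The number as deposited reaches 263 higher and 68 lower at 380 min, and 21 higher and 172 lower after centring.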

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

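The tests of dye bias, of exchanged labels and of the sample identity of arrays, and the test of a shift of all targets for pan1, were chosen only after the results were seen; the single-spot test of pan1 was set beforehand. Of 37 checked genes and groups, 2 held a transition time point far from the other 3, where chance gives about 1 in 20, and the group of 11 low oxygen time points was too large for this check. For cmk the 20 min value (-0.0343, against 0.00337 for the nearest) left a gap of 0.955 of the whole range. For proS the 0 min value (0.0289, against -0.0953 for the nearest) left a gap of 0.889 of the range.

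The gene pan1 rose while psmA and psmB, for the proteasome core it serves, did not. Its change exceeded that of psmA by 0.365 and that of psmB by 0.417, values that restate the pattern on genes chosen for it. A defect of single spots is argued against, since its 8 changes (4 spots in each of 2 orientations) ran from 0.272 to 0.383. A shift of all targets is argued against too, since 0.276 remained after median-centring. The rise may be biological, as a hypothesis only, because oxygen, time and culture age moved together in 1 culture.

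The arrays of 20, 25 and 35 min with the sample in Alexa 647 resembled the arrays of 0 min. Their deviations from the mean of the other 12 time points correlated with the Alexa 532 array of 0 min at 0.781, 0.763 and 0.737. The Alexa 647 arrays of 10 and 45 min reached 0.53 and 0.553, so some likeness was not confined to these 3 arrays. Their deviations correlated with the mean dye profile of the other 12 time points at -0.671, -0.601 and -0.599 (median -0.601) while their partners stood at -0.231, 0.405 and 0.240, as a stronger dye bias would give, but the 0 min arrays themselves stood at -0.651 and -0.487, so RNA of 0 min would give it too, and across the 672 targets with the smallest dye difference they still correlated with the 0 min array at a median r of 0.677, which argues against dye bias along that profile as the whole cause. An exchange of labels with the 5 and 10 min arrays would call for high correlations of those with 532 arrays of 20 to 35 min: over all targets these reached 0.213 and 0.35, below the partners' own 0.392 and 0.540, and over the 672 targets 0.353 and 0.440, below 0.639 and 0.507, but the bound of 0.5 set for this test decides nothing, since the pairs of 30, 45, 55 and 70 min reach only 0.163 to 0.382. Whether the 3 arrays hold RNA of 0 to 10 min cannot be told apart from poor measurement: 145 targets that moved alike in both orientations stood at a median of 0.161 of their later change (0.161, 0.0209 and 0.475 at 20, 25 and 35 min), with quartiles from -0.409 to 0.528 at 25 min. Without these 3 time points 852 targets were called between phases.

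The 532 array of 200 min carries a source name of 5 min while its title gives 200 min. Its profile correlated at 0.834 with that of 5 min and at 0.915 to 0.927 with those of 110, 160, 290 and 380 min, a gap of 0.081 from the lowest of these, which argues against its holding the 5 min sample. No biological explanation was tested for this array.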

How the results depend on the processing

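The runs with zeros kept, with the dye profile removed, without 20, 25 and 35 min (also on one dye), against genes with a symbol only and, for slopes, with centred lists, time points left out of lists and genes, and other settings of named genes were chosen after seeing the data. The cause of each difference below was not tested unless the setting itself removes samples.

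For the phase, 785 called targets became 333 after centring, 151 after scaling, 34 on 647 arrays alone (1025 on 532 arrays), 98 on those without 20, 25 and 35 min, 430 with 352 targets of large orientation gap removed, 181 with zeros kept, 153 with the dye profile removed, 1559 with low oxygen limited to 110 to 380 min, 137 with 25 to 70 min, 13 with a 2-fold limit and 274 by the exact permutation test (269 shared). Leaving out 1 transition time point gave 60 (without 0 min) to 597, with 193 without 20 min, and leaving out 1 low oxygen time point 599 to 1053. For the time course, 1503 became 970 after centring, 523 after scaling, 894 on 647 arrays, 929 with zeros kept and 550 with the dye profile removed, with 1059 to 1547 when 1 time point was left out. For the slope, 1110 became 582 after centring, 448 after scaling, 151 on 532 arrays (1448 on 647 arrays), 453 with zeros kept and 417 with the dye profile removed, with 635 (without 380 min) to 1148 when 1 was left out. Changes of 2-fold at 380 min went from 331 to 193 after centring. Without the doubted pairs the counts were 852 (phase), 1425 (time course) and 866 (slope).

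Of 2 lists between phases, camera kept 0 with an estimated correlation (2 at unadjusted p), 0 after centring (3 unadjusted), 0 against genes with a symbol (2 unadjusted), 0 with 25 to 70 min (2 unadjusted), 1 on 532 arrays, 1 on 647 arrays and 1 with 110 to 380 min. Fry, which compares no list with other targets, called neither of these (adjusted p = 0.169 and 0.257) but 1 other, phototrophy. Leaving out 1 time point gave 0 (without 0 min, 3 unadjusted) to 3. For slopes, 1 list became 0 with an estimated correlation (1 unadjusted), 0 against genes with a symbol (1 unadjusted) and 2 on 647 arrays, with 1 to 2 when 1 time point was left out (2 without 290 min), while fry called 6 of 15. Its downward calls, TCA cycle and glycolysis, held after centring (adjusted p = 0.000456 and 0.00438). The upward ones did not: phototrophy (0.429), motility and chemotaxis (0.203), histidine synthesis (0.722) and other amino acid synthesis (0.780). Centring also brought fry calls for lists not called as deposited.

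The uncalled difference of phoU (0.00386) reversed to -0.0400 after centring, -0.0195 on 647 arrays, -0.00872 without 0 min and -0.000912 without 5 min (0.0205 without 20 min, and 0.0272 on 532 arrays), and the uncalled slope of bat to -0.00685 on 532 arrays, while it passed on 647 arrays (0.0653, adjusted p = 0.00471). Uncalled proS, sdhC and hisG passed the phase test on 532 arrays, and mdh and cbiQ after centring. Of 18 called phase genes 8 passed after centring, 14 on 532 arrays and 1 on 647 arrays, and pan1 passed in all 7 settings run for it (adjusted p = 3.79e-05 to 0.0157). No paired analysis was possible because each time point was sampled once and no number links a transition sample with a low oxygen one.

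Of 100 splits of the 15 time points drawn, 2 called at least 785 targets, the real one included. The other set 110, 160, 290 and 380 min apart and called more, so a split of late from earlier time points was as strong. For the time course 1 of 100 orders (highest other 854) and for the slope 1 of 100 (highest other 18) reached the real count. Shares this small argue against a random choice or order of time points. They cannot exclude a slow drift or errors shared by neighbouring samples, since all samples came from 1 culture in series. As many lists as the real 2 came from 21 of 100 splits (highest other 4), and as many as the real 1 from 37 of 100 orders (highest other 2), so chance cannot be excluded for either.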

Other observations

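The comparison of genes with and without a symbol, the choice of the genes and targets named here and the weighing of both tests together were made only after the results were seen. Outside the lists, the genes msrA for methionine sulfoxide reductase (0.0918, adjusted p = 0.0419, 11 of 11 time points), truA for a tRNA pseudouridine synthase (0.0984, adjusted p = 0.0295, 11 of 11) and cca for the enzyme that adds CCA to tRNA (0.102, adjusted p = 0.0383, 10 of 11) also rose between phases as deposited, but after centring they stood at 0.0480, 0.0546 and 0.0580 and did not pass (adjusted p = 0.223, 0.122 and 0.219). After centring, lysS for lysyl-tRNA synthetase (-0.105, adjusted p = 0.0241, 10 of 11 time points lower as deposited) and infB for a translation initiation factor (-0.125, adjusted p = 0.0342, 8 of 11) were lower in low oxygen, as were mdh (-0.143, adjusted p = 0.0382, 11 of 11) and cbiQ (-0.101, adjusted p = 0.0396, 11 of 11), none of which passed as deposited. Among 479 targets past both the phase and the slope test, 425 were higher and 53 lower in both and 1 had opposite signs, and 11 genes with a symbol passed both. These counts are as deposited, and the upward majority did not hold in either test after centring (148 higher and 185 lower between phases, 176 and 406 for the slope).

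The largest phase differences lay among targets without a symbol. Of these, target2511 (first spot 5021) rose by 0.563 and target2399 (first spot 4797) by 0.434, with adjusted p = 0.00144 and 0.00690, while target925 (first spot 1849) stood at -0.612 and target543 (first spot 1085) at -0.415, with adjusted p = 0.0258 and 0.00541. All 4 had slopes of the same sign as their phase difference, and all 4 held after centring.

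The 132 tested genes with a symbol had a median phase difference of 0.0205, against 0.0546 for targets without one. Of 10000 random lists of 132 targets 0% had a lower median (lowest 0.0249), as a description of these arrays. Genes with a symbol are therefore no random sample of the array, and shares among them do not carry over to all targets.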
